A study of Mus musculus with 2 samples.

How the data were processed

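The data were peak lists from 2 CUT&Tag libraries for H3K9me2 in activated B cells of C57BL/6 mice, 1 wild type and 1 Jmjd1c B cell knockout, made with a commercial transposase kit per the labels' protocols. Samples were grouped by the genotype in the labels. The submitters' processing notes name Trim Galore 0.6.6, Bowtie2 2.4.2, SAMtools 1.11, Picard, MACS2, HOMER, deepTools and the mm10 build, without their roles.

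Per the file headers, the authors called peaks separately in each library with MACS2 2.2.7.1 in broad mode, with q and broad cutoffs of 0.01, all duplicate tags kept, no control library, an effective genome size of 1870000000 bp and a local background window of 10000 bp. Per the file headers, total tags numbered 33474010 in WT and 34502392 in KO, with tag sizes of 149 and 148 bp, paired-end mode was off, and the modelled fragment length d was 292 and 189 bp. Per the file headers, the caller also listed alternative lengths, among them 191 bp for WT and 293 bp for KO. The caller extends each tag to d, so d sets the smallest peak, and pileup, width, q-value and fold enrichment depend on it. The deposited pileup column is a coverage signal of extended tags, not scaled between libraries. The deposited p-value and q-value columns are given as −log10 by the authors' caller, and fold enrichment is the authors' ratio of pileup to the local background. These columns were used to rank peaks within a list and to filter both lists at the same cutoffs of q or pileup. Counts at such a shared cutoff are not free of the differences in d and depth. A domain much wider than the background window raises its own background and can be missed, kept duplicates can make narrow towers of reads, and without a control, regions that attract reads in any library stay in the lists.

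Peaks on chromosomes 1 to 19, X and Y were analysed. Gene positions came from RefSeq genes of GRCm38.p6, the assembly behind mm10, with 49595 genes on these chromosomes, of which 21774 are protein-coding. That table lists genes of unplaced and patch scaffolds under their chromosome's number, and 348 such genes, told apart by the break in the order of starts, were left out. Chromosome spans ran between the outermost gene or peak. Coordinates count from 1.

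The comparisons, gene lists, processing alternatives and the rule for named genes were fixed before the data were examined. Covered length is the union of the peaks of a list. Overlap needed at least 1 bp, and chance overlap came from 100 shuffles within chromosomes and, added after seeing the data, from moves of 5 to 50 kb. The design asked for promoters and for windows starting upstream of each gene, with exons and introns. Strand and exons were not used here, so windows of 1 kb around either gene end, gene bodies with 2 kb on both sides, and classes inside and outside gene bodies took their place. The gene lists held plasma cell, B cell identity, germinal centre, STAT3 and cytokine signalling, B cell activation, H3K9 methylation enzyme and reader, housekeeping, T cell and innate lymphoid, myeloid and neuronal genes, and 10 families were taken by symbol. All list symbols matched the gene table. The mean change in covered share of a list was set against 10000 random lists drawn from the 200 nearest genes in covered share and window length; the list median that the design names was 0 points in all but the neuronal list, where it was -0.0766 points, at percentile 18.6 of its random lists.

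Named genes were members of the fixed lists, the 10 largest gains and 10 largest losses of covered share among genes with a window of at least 20 kb, and the 5 peaks of highest fold enrichment in each list, merged within 10 kb. Gains and losses had to keep their sign at a q of 1e-05 or lower, with predicted genes and genes within 100 kb of one already named on that side skipped, and multigene family members marked as uncertain. Values of some single genes are not reported here.

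With 1 library per genotype no p-value was computed. Shares carry exact Clopper-Pearson intervals and counts exact Poisson intervals, and ratios of counts carry exact binomial-based intervals. Kept duplicates and uncontrolled calling mean that these cover counting error only. Depth was nearly equal, with a KO to WT ratio of 1.03 in tags. Alternatives were a stricter q, peaks merged within 5 kb, peaks at least 1 kb wide, autosomes only, equal numbers of peaks, reciprocal overlap of 50%, 25% of a peak covered, gene ends with 5 kb, at least 50% of the end window covered, windows with 10 kb and random lists matched on length only. Random swaps of genotype per site, widening KO peaks by the difference in d and leaving out peaks of a pileup of 100 or more were added after seeing the data.

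The interval functions were checked against direct enumeration and tested on simulated data. In a WT list with 60% of its peaks left in place and the others moved, 60.6% were recovered as overlapped. In a simulated WT to KO comparison over 21774 genes, with 6 peaks planted in each of 200 genes, 100% of these genes showed a gain above 5 percentage points. The planted peaks were 1 kb wide in an otherwise unchanged copy of the WT list, which nearly fixed this outcome in advance. It checks the arithmetic and not the sensitivity to smaller gains. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.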

Results

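H3K9me2, the dimethylated form of lysine 9 of histone H3 that marks repressed chromatin, was mapped in activated mouse B cells of the C57BL/6 strain by CUT&Tag, in which an antibody directs a tagging transposase to the marked chromatin. There were 2 libraries, 1 from wild-type cells (WT) and 1 from cells of a B cell Jmjd1c knockout (KO). Jmjd1c encodes a jumonji-domain protein of the family that holds H3K9 demethylases, and the comparison asks where H3K9me2 differs between the genotypes. The WT peak list rested on 33474010 tags and the KO list on 34502392 tags. Each genotype had a single library, so no difference below has a replicate check and no p-value was computed. Random lists, swaps and bootstraps describe these 2 libraries only. Intervals are 95% intervals for counting error only and treat the lists as independent, although many sites are in both, so those of ratios are too wide.

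At Jmjd1c itself, on chromosome 10 from 67096351 to 67256326, neither library had an H3K9me2 peak in the gene body or within 2 kb of it, so these lists do not check the knockout. Across chromosomes 1 to 19, X and Y, the WT library had 31623 peaks and the KO library 32149, a KO to WT ratio of 1.02 (1.001 to 1.033). Peak density was highest on chromosome 3, with 16.5 peaks per Mb in WT and 16.9 in KO. It was lowest among the autosomes on the gene-dense chromosomes 19 (5.78 and 6.28 per Mb), 11 (6.55 and 6.75) and 7 (7.90 and 7.79). The Y chromosome held 1 peak in each library. The KO to WT ratio of peak number ran from 0.957 on the X chromosome (0.900 to 1.018, 2094 and 2004 peaks) to 1.09 on chromosome 19 (0.934 to 1.26). For 0 of the 21 chromosomes did the interval exclude the ratio over all chromosomes. In a comparison paired by site, added after the data were seen, genotype was swapped at random 1000 times between sites with the same peak numbers. The differences on chromosomes 8 (1307 WT and 1408 KO peaks), 13 (1801 and 1740) and X lay outside the central 95% of swaps, and 0 to 3 chromosomes did so in 95% of the swaps themselves.

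**Figure D1:**
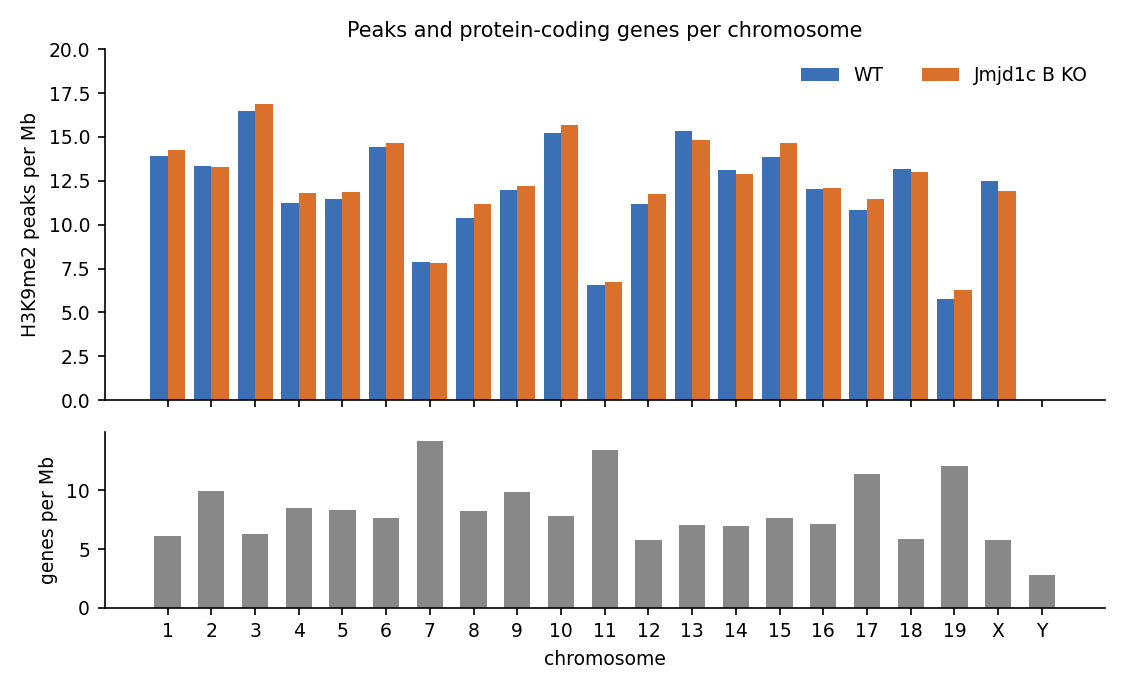
Upper panel, H3K9me2 peaks per Mb on each chromosome in WT (blue) and KO (orange), 1 library each; lower panel, protein-coding genes per Mb. Chromosome 3 had the most peaks per Mb and chromosome 19 the fewest among the autosomes in both libraries.

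The peaks covered 17.95 Mb in WT and 14.74 Mb in KO, a ratio of 0.821. This was only 0.675% and 0.554% of the span analysed. Peaks were wider in the WT list, with a median width of 486 bp against 376 bp and a mean of 568 bp against 458 bp. The caller had used an estimated fragment length, d, of 292 bp for WT and 189 bp for KO, which was also the smallest peak width in each list. After d was subtracted, the mean width was 276 bp in WT and 269 bp in KO, a ratio of 0.977. With each KO peak widened by the 103 bp difference in d, an alternative chosen after the data were seen, the covered ratio was 1.005. At a stricter threshold, a q of 1e-05 or lower, WT had 4110 peaks and KO 2603. The q-values depend on d as well, so these counts are not free of the difference in d.

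**Figure D2:**
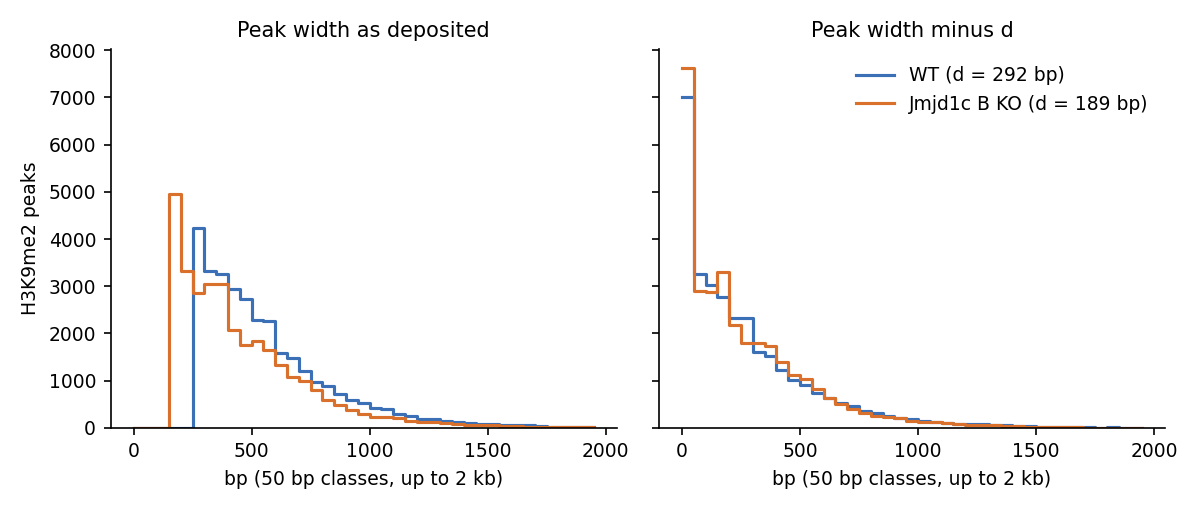
Number of H3K9me2 peaks by width in 50 bp classes for WT (blue) and KO (orange), as deposited on the left and after subtraction of each library's fragment length d on the right. The medians as deposited were 486 and 376 bp, and the means after subtraction were 276 and 269 bp.

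Of the WT peaks, 14678 (46.4%, 45.9 to 47.0%, exact binomial interval) were overlapped by a KO peak by at least 1 bp. In the other direction 14746 KO peaks (45.9%, 45.3 to 46.4%) were overlapped by a WT peak. Shuffling the other list within its chromosomes 100 times gave 1.33% and 1.31%, and moving its peaks by 5 to 50 kb gave 4.47% and 4.40%. The base pairs in common made up 23.3% of those covered in either list. The overlapped share of WT peaks was 26.1% in the 10% of the list with the least significant q-values from the authors and 81.8% in the most significant 10%, and that of KO peaks was 25.8% and 73.7%. Among peaks at the stricter threshold, 892 of 4110 in WT and 630 of 2603 in KO had no overlapping peak in the other full list.

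**Figure D3:**
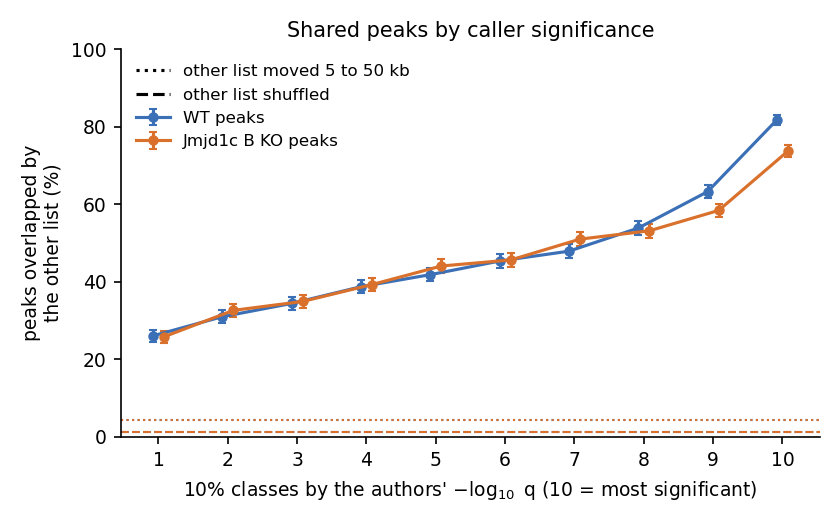
Share of peaks overlapped by a peak of the other list, in 10 classes of equal size by the authors' −log10 q, with exact 95% binomial intervals; dotted and dashed lines give the overlap after the other list was moved by 5 to 50 kb or shuffled. The WT share runs from 26.1% in the least significant class to 81.8% in the most significant, and the KO share from 25.8% to 73.7%.

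The highest fold enrichments, which are the authors' values and were used only within a list, lay at the same narrow sites in both libraries. In WT they were at chromosome 5 from 147611293 to 147611735, inside Flt1, a receptor for vascular endothelial growth factor (22.4-fold), at chromosome 8 from 83756676 to 83757130 (21.9-fold), 15.4 kb from Adgre5, and at chromosome 17 from 67741222 to 67741671, inside the laminin chain gene Lama1 (21.5-fold). The next were at chromosome 2 from 92093465 to 92093931 (21.2-fold), 69.3 kb from Creb3l1, and at chromosome 12 from 3109726 to 3110209 (20.2-fold), 137 kb from Rab10. The KO list was led by peaks at the sites near Adgre5 (38.2-fold) and Creb3l1 (36.1-fold) and inside Flt1 (36.0-fold) and Lama1 (34.5-fold). The last of its 5 leading peaks, at chromosome 11 from 121982303 to 121982599 (32.8-fold), lay beyond the last protein-coding gene and also overlapped a WT peak. The pileups of these peaks ran from 4155.6 to 54547.7 in WT, against a median of 25.3 over the list, and from 3304.5 to 66281.3 in KO, against 19.1. With duplicate tags kept and no control library, such narrow peaks can be towers of reads and need not mark H3K9me2.

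In 1 Mb bins, H3K9me2 peaks lay mainly in gene-poor regions in both genotypes. The 292 bins with no protein-coding gene held a mean of 17.5 peaks in WT and 17.5 in KO, the 344 bins with 15 to 29 genes held 3.63 and 3.83, and the 115 bins with 30 or more genes held 4.86 and 4.90. The densest bins were chromosome 1 from 145000001 to 146000000, with 109 WT and 110 KO peaks, chromosome 10 from 15000001 to 16000000, with 101 and 118, and chromosome 5 from 11000001 to 12000000, with 108 and 109. The first 2 held no protein-coding gene and the last held 4. Peak numbers of the 2672 bins had a Pearson correlation of 0.970 between the libraries, against -0.0535 to 0.0514 for 95% of rotations along the genome; the bins are not independent replicates. The largest gains in KO were from 63 to 85 peaks on chromosome 1 from 96000001 to 97000000, from 18 to 39 on chromosome 2 from 124000001 to 125000000, and from 47 to 67 on chromosome 8 from 54000001 to 55000000. The largest losses were from 73 to 56 peaks on chromosome 2 from 48000001 to 49000000, from 53 to 36 on chromosome 7 from 74000001 to 75000000, and from 57 to 40 on chromosome 14 from 94000001 to 95000000. They were no larger than random swaps of genotype per site gave, with a largest gain of 15 to 26 peaks and a largest loss of 15 to 25 in 95% of 1000 swaps.

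**Figure D4:**
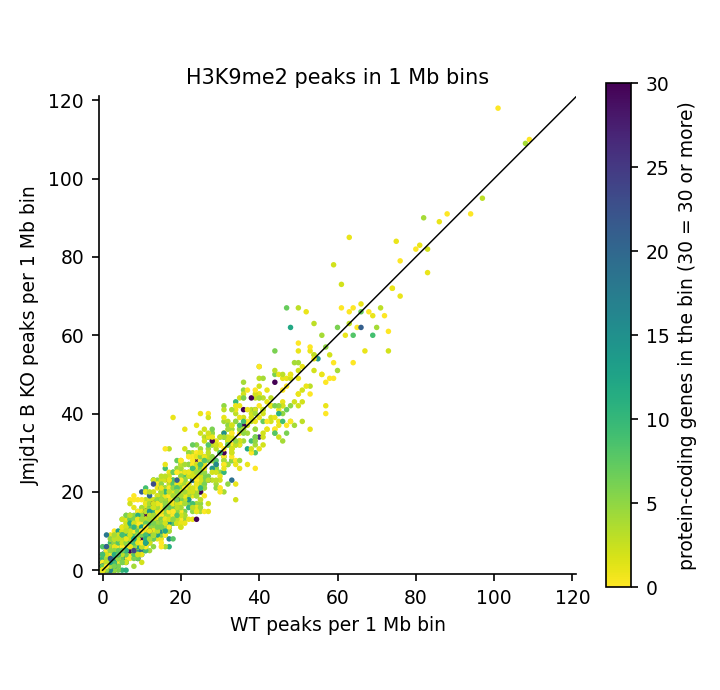
H3K9me2 peaks in each of 2672 bins of 1 Mb in WT (x axis) and KO (y axis), coloured by the number of protein-coding genes in the bin; the line marks equal numbers. The Pearson correlation was 0.970, and the bins with most peaks hold few genes.

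Protein-coding gene bodies held 29.01% of WT peak midpoints (28.5 to 29.5%) and 29.1% of KO midpoints (28.6 to 29.6%), and made up 38.7% of the span analysed. Sequence outside annotated genes held 62.1% and 62.2% and made up 53.3%. Peaks within 1 kb of an end of a protein-coding gene were rare, with 2.14% of WT and 2.15% of KO midpoints against 2.96% of the span. Of 21774 protein-coding genes, 482 had a peak there in both libraries, 306 in WT only and 281 in KO only. This near balance did not hold at the stricter q, with 97 in WT only and 27 in KO only, nor for peaks at least 1 kb wide (76 and 28) or with at least 50% of the window covered (44 and 19). These limits act on q or width, which depend on d, so the tilt toward WT was not separated from d. Without these limits, and with KO peaks widened by the difference in d, the numbers were 303 and 294. The gene table gave no strand, so either end of a gene can be its promoter.

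Genes that define B cells and their activation carried no H3K9me2 peak in either genotype. This held for all 20 genes of the B cell identity list, among them the transcription factors Pax5 and Bach2, and for the 20 B cell activation genes with Myc and Egr1. It also held for the 16 germinal centre genes, among them the transcriptional repressor gene Bcl6, and for the 16 plasma cell genes with the regulators Prdm1 and Irf4. The 21 genes of STAT3 and cytokine signalling, the 22 H3K9 methylation enzymes and readers, which include Kdm3a and Ehmt2, and the 20 housekeeping genes had none either. Windows were the gene body with 2 kb on both sides, and 0 peaks remained with 10 kb. Most genes had no peak, 88.2% of all protein-coding genes in either library. Random lists matched on window length had a median of 3 peaks over both libraries for the activation and germinal centre lists and 4 for the plasma cell list, which put these lists at percentiles 9.39, 11.5 and 7.71. For B cell identity the median was 29 peaks and the percentile 0.87, and for the H3K9 methylation enzymes and readers 11 peaks and 2.14. The STAT3 and cytokine list was at percentile 7.33 (median 4) and housekeeping at 13.29 (median 2). An absent call means only that no region passed the authors' threshold.

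Neuronal genes that B cells do not use were rich in peaks in both libraries. The 20 genes held 348 WT and 342 KO peaks, or 21.6 and 21.2 per Mb, against 8.75 and 8.92 per Mb over all protein-coding windows, and the KO to WT ratio was 0.983 (0.844 to 1.14). Dlg2, a postsynaptic scaffold gene, had 98 and 95 peaks. Cntnap2, a neurexin relative, had 90 in WT and 69 in KO, whereas the glutamate receptor gene Grin2a had 2 and 8. Among 18 markers of T cells and innate lymphoid cells, Themis, a gene of T cell selection, held 22 and 23 peaks, Bcl11b held 1 and 0, and the other 16 had none. Of 17 myeloid markers, Adgre1, which encodes a macrophage surface receptor, had 1 peak in each library and the other 16 had none.

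Peak density differed widely between large gene families. Windows of the 1109 olfactory receptor genes held 196 WT and 195 KO peaks (30.1 and 29.96 per Mb), those of 352 vomeronasal receptor genes 69 and 80 (13.9 and 16.1 per Mb), and those of 57 clustered protocadherins 20 and 20 (33.7 per Mb in both). Cytochrome P450 genes had 55 and 42 peaks (ratio 0.764, 0.499 to 1.16), zinc finger genes 89 and 69 (0.775, 0.558 to 1.07) and serpins 23 and 20 (0.870, 0.453 to 1.66). Defensins had 5 and 3 and histone genes 2 and 4. The 53 keratin and 39 Hox genes had none. Reads of near-identical family members can be placed on the wrong copy, so these family counts are uncertain. The immunoglobulin heavy chain locus Igh had 2 WT peaks and 1 KO peak over 2.75 Mb, Igk had 7 and 5, and Igl had none. Of the 20 lists and families, 9 had no peak and so no ratio. For 0 of the other 11 did the interval of the ratio exclude that of all gene windows, 1.02, and for 0 did the mean change in covered share lie outside the central 95% of 10000 random lists matched on covered share and window length. Paired by site, zinc finger genes lay outside the central 95% of swaps, and 0 to 2 of the 11 did so in 95% of the swaps themselves. The zinc finger result rested on few genes. For 397 of its 400 genes, with 71 WT and 56 KO peaks, the difference of -15 peaks lay inside, at -17 to 19.

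**Figure D5:**
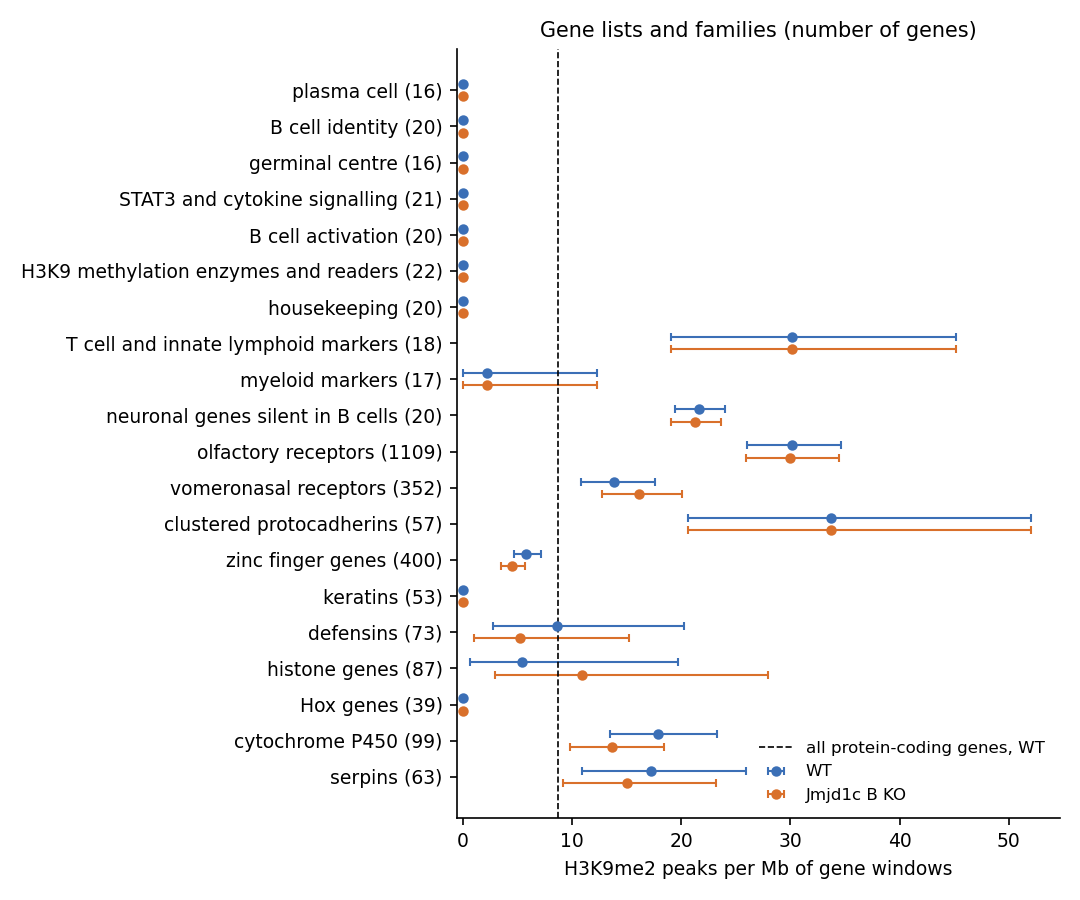
H3K9me2 peaks per Mb of gene windows (x axis) for each gene list or family, with the number of genes in brackets, in WT (blue) and KO (orange); bars are exact 95% Poisson intervals, with none drawn at 0, and the dashed line marks all protein-coding genes in WT. The B cell, STAT3, H3K9 enzyme and housekeeping lists sit at 0, and the olfactory receptors at 30.1 and 29.96.

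Single genes differed in covered share in both directions, by -25.7 to 18.8 percentage points over all genes. In windows of at least 20 kb, the largest losses by the preset rule were at Chodl, a membrane lectin gene (8.97% of its window covered in WT and 1.76% in KO, 4 and 1 peaks), and Dmp1, a bone and dentine matrix gene (8.19% and 1.98%, 3 and 1 peaks). They were followed by Trim52 (9.69% and 5.66%), Zc2hc1a (5.69% and 1.86%), Cyp2j9 (6.43% and 2.80%), Vmn2r124 (3.48% and 0%), Mroh2a (7.53% and 4.09%), Nlrp14 (4.84% and 1.46%), Tfap2b, an AP-2 family transcription factor gene (9.98% and 6.64%), and Fthl17a (3.98% and 1.28%). The largest gains were at Olfr183 (2.57% in WT and 5.68% in KO) and at Frzb, which encodes a secreted Wnt antagonist (2.06% and 5.06%, 2 and 4 peaks). Then came Clec4b1 (4.86% and 7.77%), Vmn2r23 (4.98% and 7.68%), Adgrf2 (2.56% and 4.08%), Ccdc7a (5.10% and 6.61%), Trim60 (2.43% and 3.94%), Slco6c1 (2.14% and 3.38%), the T-box gene Tbx18 (3.595% and 4.65%) and Srpx (2.36% and 3.39%). Olfr183, Vmn2r23, Vmn2r124, Clec4b1, Cyp2j9, Trim52, Trim60, Nlrp14, Fthl17a and Slco6c1 belong to multigene families and are uncertain. These 20 genes differed by at most 4 peaks between the libraries. Mroh2a (4 and 4), Fthl17a (1 and 1) and Trim60 (2 and 2) had equal numbers. Tfap2b, listed as a loss, had 5 peaks in WT and 6 in KO. Tbx18 and Srpx changed direction with 10 kb of flank. The larger d lengthens WT peaks, which tilts the values toward losses in KO. The rule itself also favours losses, since at the stricter q KO peaks covered 0.509 times the WT length. The sizes of the listed gains and losses therefore cannot be set against each other. With KO peaks widened by the difference in d, Tfap2b went from -3.35 to -1.53 points and Ccdc7a from 1.51 to 2.77 points. At the stricter q, where the rule required the sign to hold, Olfr183 went from 3.11 to 0.307 points and Zc2hc1a from -3.84 to -0.184 points. Clec4b1 went from 2.91 to 0.105 points, whereas Tbx18 went from 1.05 to 3.66 points.

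Over all 21774 genes, 1695 had a peak in their window in both libraries, 414 in WT only, 460 in KO only and 19205 (88.2%) in neither. The mean covered share was 0.338% in WT and 0.280% in KO, and this order turned around when KO peaks were widened by the difference in d.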

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

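Chosen only after the results were seen were the tests of peak width above d, of the overlapped share by q and of the variance of bin differences; the test of widened KO peaks on overlap was written before its result.

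Signal outside the chromosomes analysed comprised 4 WT and 4 KO peaks on the mitochondrial genome, with a median pileup of 408 and 396, and 183 WT and 194 KO peaks on unplaced and patch scaffolds. These peaks entered no comparison.

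KO peaks covered 17.9% less length than WT peaks. At the 14553 peaks shared one to one, the median width above d was lower in WT, with WT minus KO at -12 bp (95% bootstrap interval -17 to -7 bp). This argues against narrower H3K9me2 regions in the knockout only if d adds at least its full length to each width. If d added more than that, WT minus KO would be lower still. As deposited, the median difference was 91 bp, and it was 171 bp in the 105 pairs with a pileup of at least 100 in both. The difference in d was 103 bp, which the difference in those 105 pairs exceeded. How much d adds to a width was not measured, so the paired widths do not settle the question. The fragment length d used by the caller may account for the lower covered length, since the mean width above d had a KO to WT ratio of 0.977. The caller listed lengths of 191 and 292 bp for WT and of 189 and 293 bp for KO, and used 292 and 189 bp. Why it took different ones stays open, and peaks without a partner were not part of the paired measure.

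Most peaks had no overlapping peak in the other list, 16945 in WT and 17403 in KO. Peak edges set by the different d are argued against, as widening KO peaks by the difference raised the overlapped share of WT peaks by 0.405 percentage points. Whole 1 Mb regions gained or lost in 1 genotype are argued against as the main cause, since the variance of KO minus WT peaks across 2109 bins with peaks, 16.4, lay within the 15.1 to 17.7 of the central 95% of 1000 random swaps of genotype per site. Calls close to the caller's threshold may account for much of it, with the overlapped share of WT peaks 55.7 percentage points higher in the most than in the least significant 10% by q. Whether d decided which sites passed the threshold was not tested and stays open, as does a difference between genotypes at single sites, untested without replicates.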

How the results depend on the processing

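Widening KO peaks, leaving out peaks of high pileup and moving peaks locally were the alternatives chosen after seeing the data. The KO to WT ratio of peak number, 1.02, was reversed to 0.633 at the stricter q and 0.614 for peaks at least 1 kb wide. Both limits act on values that depend on d. The covered ratio, 0.821, was 0.509 at the stricter q, 0.896 for merged peaks, 0.615 for peaks at least 1 kb wide and 1.005, reversed, with KO peaks widened by the difference in d, which adds that length by construction. The overlapped share of WT peaks, 46.4%, was 28.2% at the stricter q, 48.3% for merged peaks, 28.3% for peaks at least 1 kb wide, 29.8% with reciprocal overlap of 50% and 43.0% with 25% of the peak covered. For KO peaks, 45.9%, the values were 44.4% at the stricter q, 48.2% merged, 29.3% reciprocal and 44.1% with 25% covered. Relative to all chromosomes, the covered ratio at the stricter q went from 0.937 to 0.780 on the X chromosome and from 1.10 to 1.51 on chromosome 19. The share of peak midpoints in protein-coding gene bodies at the stricter q went from 29.01% to 27.7% in WT and from 29.1% to 27.3% in KO. Genes with a peak at an end in 1 genotype only, 587, numbered 124 at the stricter q (97 in WT only), 104 with peaks at least 1 kb wide (76), 1036 with 5 kb windows (510) and 63 with at least 50% of the window covered (44). The mean change of gene windows, -0.0579 points, was -0.0300 at the stricter q and reversed to 0.00384 with widened KO peaks. Lists with a mean change outside the central 95% of random lists, 0 of the 11 with peaks, became 1 with 10 kb of flank (histone genes) and 1 with matching on length only (serpins). The rule for named genes required their sign to hold at the stricter q. Of 60 values of the 20 genes under the other 3 alternatives, 58 kept their sign, and with 10 kb of flank Tbx18 reversed to -0.198 and Srpx to -0.204 points. A kept sign does not mean a kept size. With 10 kb of flank Fthl17a went from -2.69 to -0.111 points and Ccdc7a from 1.51 to 2.47 points. The other 21 alternative values moved less. These were 6 ratios, held to the counting interval of peak numbers, 9 overlapped shares, held to the binomial interval, 3 differences of shares, held to a 95% normal interval, and 3 counts, held to 1.5 times. Among them, KO minus WT in the share of midpoints in protein-coding gene bodies changed sign at the stricter q. It went from 0.048 to -0.412 points, inside its interval of -0.657 to 0.753. Except for widening, the cause was not tested. Replicate libraries could not be paired because each genotype had 1 library, and the effect of depth on calls near the threshold was not tested.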

Other observations

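The 153 groups by symbol, the swaps of genotype per site, the long genes, the X chromosome and the tests of window length and gene-rich surroundings were chosen after the data were seen.

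Among 153 groups of at least 15 genes that share the start of their symbol, those with most peaks per Mb were the protocadherin beta genes (Pcdhb), with 10 WT and 9 KO peaks in 0.147 Mb, the prolactin family (Prl), with 19 and 13 in 0.313 Mb, the late cornified envelope genes (Lce), with 7 and 6 in 0.131 Mb, and the Akr genes, with 15 and 13 in 0.398 Mb. Semaphorin genes (Sema) had 68 and 92 peaks, a ratio of 1.35 (0.978 to 1.88). For 0 of the 120 groups with a peak did the interval of the ratio exclude that of all peaks. Many groups had too few peaks for this, with an interval of 0.0127 to 78.5 where each library had 1 peak. Paired by site, Sema, Rnf (15 and 7 peaks) and Tspan (10 and 3) lay outside the central 95% of random swaps, against 0 to 6 groups in 95% of the swaps themselves. In the other 33 groups neither library had a peak. Among them were the 53 Rpl, 44 Rps, 49 Mrpl, 28 Polr and 21 Nup genes, most of which serve ribosomes, RNA polymerases or the nuclear pore, and also the tissue-restricted 53 Krt, 33 Rhox and 18 Wfdc genes.

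Not all long genes had a peak call, and an absent call need not mean an absent mark. Of the 227 genes with a window of at least 500 kb, 26 (11.5%) had no peak in either library, among them Auts2, Wwox, Inpp4b and Arhgap15, whereas Csmd3 held 75 WT and 68 KO peaks and Magi2 65 and 66. Dgkb, which encodes a diacylglycerol kinase, had 44 and 60.

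In 7 of the 10 fixed gene lists neither library had a peak. Window length is argued against as the whole cause, since 0% of 10000 draws of all 10 lists, with each gene replaced by one of like window length, had as many lists without peaks, and the most was 6. Gene-rich surroundings are argued against as the whole cause for all lists together as well, at 0% of 10000 draws. These were matched also on the number of genes in the same 1 Mb, again with at most 6. Taken singly, random lists of like length had no peak in 1.69% of draws for B cell identity and 26.6% for housekeeping, and the myeloid list, whose genes B cells do not use, held 2 peaks against a median of 3. Matched also on gene number, these shares were 1.22% for B cell identity and 32.45% for housekeeping. They were 7.68% for H3K9 enzymes and readers, 9.21% for plasma cell and 10.85% for germinal centre. For B cell activation and STAT3 they were 20.93% and 28.74%, so gene-rich surroundings stay possible for single lists. Base composition, mappability and expression were not analysed here and stay open, and no biological explanation was tested.

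The KO to WT ratio of peak number on the X chromosome was 0.937 times that on the other chromosomes, against 0.954 to 1.0496 for the central 95% and 0.930 to 1.08 for all of 1000 random swaps of genotype per site; X was singled out as the lowest of 21 chromosomes. A pileup of 100 or more was reached by 135 WT and 115 KO peaks, of which 135 and 111 overlapped a peak of the other list.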
